A study of Mus musculus with 2 samples.

How the data were processed

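RNA of pancreatic islets from control and RbΔK7 knock-in mice was hybridised to 2 two-colour Agilent mouse gene expression arrays, each with 1 control sample (Cy3) and 1 mutant sample (Cy5), as the labels give the dyes. Islets were released with collagenase and picked by hand under a microscope, per the labels' protocols. The series design states 2 control and 2 mutant samples, harvested independently. Images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers, and the headers give probe positions on mm9. Per the file headers, the deposited intensity values are the mean signal of each spot and the median of its local background in each channel, and processed signals that the software had corrected for background, detrended and dye-normalized (linear and lowess). The deposited log10 ratios are those of red (Cy5, mutant) over green (Cy3, control) processed signals, per the file headers. The authors' series matrix holds the same log10 ratios: the largest difference from the scanner files was 0 on both arrays, so its scale and direction are settled, and its column medians were 0 and 0. Feature Extraction's p-value of each log ratio, deposited per the file headers, covers technical error within 1 array.

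Mean signals and median local backgrounds were corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50, and log2 ratios were normalized within each array by loess (span 0.3, control spots at weight 0). Control spots and non-uniformity outliers (4 gene spots on each array) were left out, saturated spots would have been kept (0 were found), and spots of 1 probe were averaged. A probe was tested when it was well above background in 1 channel or the other on both arrays. The offset draws the ratios of dim probes towards 0, so their fold changes are understated, and loess assumes that at each brightness most probes are alike in both channels. With median centring in place of loess the medians of the tested probes were 0.39 and 0.84, and the cause of this shift was not tested. The ratio within an array is the pairing of mutant and control, and the 2 ratios of a probe were tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 22266 tested probes and a threshold of 0.05. With 2 arrays each probe has 1 residual degree of freedom, to which the prior adds 4.90 (prior SD 0.204). On simulated ratios of 22266 probes, this step recovered 2.99% (2) of the probes changed by 0.5 on the log2 scale. It recovered 52.7% (39) of those changed by 1 and 100% (59) of those changed by 2. Beside these it made 16 false calls, and it called 3 probes where none was changed. The simulated errors were independent, with no dye bias shared by the arrays, so false calls from such a bias are not counted. They were drawn from the fitted prior with the same spread on both arrays. The real log2 ratios had SDs of 0.293 on the replicate 1 array and 0.478 on the replicate 2 array. So these counts hold for the fitted model and do not check it.

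Probes were named through a reference table of the GRCm38.p6 assembly, used for names only: 26762 of the 55681 probes by accession, 3819 by symbol and 634 by a synonym of 1 gene, while 24466 kept the name in the files. Positions within exons or UTRs were not analysed here. Of the tested genes, 3970 had several probes, and the probe of highest mean intensity stood for the gene. The 28 gene lists (685 genes) covered the Rb and E2F families, G1/S, G2/M, CDK inhibitors and senescence, p53 targets, beta cell transcription factors, insulin secretion, other endocrine cells, disallowed and dedifferentiation genes, and markers of acinar, duct, leukocyte, endothelial, stromal, adipose, Schwann and erythroid cells. They also covered the Reg family, antioxidant, oxidative phosphorylation, glycolysis and hypoxia, ascorbate, endoplasmic reticulum stress, interferon, dissociation stress, sex-linked, ribosomal protein and myogenic genes. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera sets the genes of a list against all other genes. At this preset correlation its p mainly measures spread over genes, and not how well the 2 pairs agree. By this test 10 lists were higher and 4 lower, with an estimated correlation 0 passed (0 also at an unadjusted p under 0.05), and 0 passed with fry, which tests a list on its own. With an estimated correlation the adjustment gave these 14 lists 1 shared value, 0.639. Their unadjusted camera p ran from 0.0665 for G1/S to 0.411 for other endocrine genes. That correlation is estimated from 1 residual degree of freedom. On simulated ratios camera called 0 lists where none was shifted. The simulated genes were independent of each other, so this does not check the preset correlation. A mean and camera's direction differ in sign only for the myogenic list of 2 genes.

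Designs, lists, thresholds and alternatives were chosen before the data were examined. The text names the 12 genes with the largest and the 12 with the smallest mean ratio among those past the threshold with 1 sign on both arrays. Where fewer passed, places were filled by the larger of the smaller ratio of the 2 arrays, and names that are only an accession, clone or predicted locus were counted and not named (72 of the 77 symbols that rose can be named). Rb1, sex-linked genes, Ins1, Ins2, Gcg, Pdx1 and up to 4 members of each list were also fixed. Values are given as replicate 1 then replicate 2, and SD is over the 2 arrays. Alternatives were Agilent's processed signals, no background subtraction, an offset of 0, median centring, quantile normalization between arrays, the series matrix values, 2 other filters on dim probes, outlier spots kept, each replicate left out, a trended and robust prior, an adjusted p under 0.1, separate channels with and without the array as a block, Agilent's own p under 0.01 on both arrays, a 1.5-fold limit, and for lists an estimated correlation, ranks, fry and the mean of a gene's probes. Leaving out population outlier spots, and leaving out acinar and Reg genes, were added later. Both arrays lie on 1 slide and each holds both genotypes, so no slide term was fitted. Data for figures were drawn from the same tables.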

Results

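Gene expression was compared between pancreatic islets of control mice and of knock-in mice that carry RbΔK7, a form of the retinoblastoma protein that resists phosphorylation. Rb binds E2F transcription factors and holds back entry into S phase until cyclin-dependent kinases phosphorylate it. The question was which transcripts differ in islets when Rb cannot be phosphorylated in the normal way. Each of 2 arrays carried 1 mutant sample labelled with Cy5 and 1 control sample labelled with Cy3, so the data were 2 log2 ratios of mutant over control per probe, from 2 independently grown and harvested pairs. Both arrays lay on 1 slide, and no pair had its dyes exchanged, so a difference between genotypes and a difference between dyes cannot be told apart for a single probe. Each array held 59305 gene spots of 55681 probes. In the control channel 37.0% of spots on the replicate 1 array and 38.1% on the replicate 2 array were well above background, and in the mutant channel 41.0% and 48.2%. No gene spot was saturated, and the number of arrays limits the precision of every value.

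Rb1, the gene that carries the mutation, had log2 ratios of 0.48 on the replicate 1 array and 0.14 on the replicate 2 array, a mean of 0.31 ± 0.24 (SD, n = 2; limma adjusted p = 0.517). Its only tested probe was spotted 10 times and lies on chromosome 14 from 73595408 to 73595467 (mm9). Whether this probe tells mutant from wild-type mRNA was not examined, so the value does not check the labels. With median centring of each array in place of loess, Rb1 had a mean of 1.04 with limma adjusted p = 0.0158, a setting in which the median of all tested probes was itself 0.39 on the replicate 1 array and 0.84 on the replicate 2 array.

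Collagen genes and other stromal genes, the neuropeptide genes Tac1 and Vip, and 4 of the MCM helicase genes rose in the mutant islets, with 1 sign on both arrays. Of 22266 probes tested with limma, 82 rose and 3 fell in the mutant at an adjusted p under 0.05. The fibrillar collagen gene Col1a1 (chromosome 11, 94813115 to 94813174, mm9) rose 5.26-fold, with log2 ratios of 2.66 and 2.13 (mean 2.40 ± 0.37, SD, n = 2; limma adjusted p = 0.0262). After quantile normalization between arrays, its log2 levels were 7.53 and 10.19 in the control samples and 10.18 and 12.33 in the mutant samples. The control sample of replicate 2 thus lay at the level of the mutant sample of replicate 1. The SD is of the within-array ratios and does not cover this difference between samples. Col1a2 rose by a mean log2 ratio of 2.54 ± 0.65, Col3a1 by 2.17 ± 0.73, and Dcn and Lum, which encode small proteoglycans of the collagen matrix, by 2.29 ± 0.57 and 2.18 ± 0.55 (SD, n = 2 each). Tac1, the precursor of substance P, rose by 2.36 ± 0.56, and Vip, which encodes vasoactive intestinal peptide, by 2.29 ± 0.56 (SD, n = 2 each; limma adjusted p = 0.0297 for both). Crispld2, which encodes a secreted protein, rose by 2.29 ± 0.21 on the brighter of 2 probes (chromosome 8, 122575417 to 122575476, mm9), and both probes passed the test. Inmt, an N-methyltransferase gene, rose by 1.94 ± 0.20, Serpinf1, which encodes pigment epithelium-derived factor, by 1.85 ± 0.14, the growth factor gene Gas6 by 1.66 ± 0.17 and the water channel gene Aqp1 by 1.64 ± 0.28 (SD, n = 2 each). Only 1 of the 2 probes of Serpinf1 passed. In the control channel Tac1, Lum, Inmt and Serpinf1 were well above background on 1 of the 2 arrays, so the size of their rise depends on how background is handled. With Agilent's processed signals their means were 3.91, 3.23, 3.58 and 2.85, and none of the 4 passed (limma adjusted p from 0.228 to 0.379).

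The largest fall among the 3 probes was that of Trpm5, a calcium-activated cation channel gene of taste cells and beta cells, with log2 ratios of -1.72 and -1.83 (mean -1.77 ± 0.077, SD, n = 2; limma adjusted p = 0.0262). Its probe is placed on chromosome 7 from 150257434 to 150257456 (mm9). The immediate early gene Egr1 (chromosome 18, 35024395 to 35024454, mm9) fell by a mean log2 ratio of 1.26 ± 0.18 (SD, n = 2; limma adjusted p = 0.0446). Its normalized log2 levels were 11.58 and 8.72 in the control samples and 10.45 and 7.33 in the mutant samples. The control samples thus differed from each other by more than this fall, which the SD of the ratios does not cover. The third was 1 of 3 probes of Chmp4b, named after its values were seen, with a mean of -1.12 (limma adjusted p = 0.0469), while its other probes had means of -0.09 and -0.17. The next genes in the rule for the lower side did not pass. Malat1 had ratios of -1.17 and -2.16, and a probe of it that carries the name NEAT2 had -1.16 and -2.32. Fos had ratios of -0.93 and -2.33, Tatdn2 -1.04 and -0.88, Ddit4 -0.88 and -1.26, Padi2 -0.77 and -1.66, and Btg2 -0.76 and -1.17. The histone gene H2bc4 had ratios of -0.78 and -0.81, and a mean of 0.11 with median centring. The acinar genes Ctrc (-2.14 and -5.42) and Reg3b (-0.92 and -5.90) also came under this rule.

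Ratios of at least 2-fold in 1 direction on both arrays were found for 108 probes higher and 10 lower in the mutant, against 2.99 and 0.652 if the 2 arrays were independent. Over all tested probes the 2 arrays correlated with Pearson's r of 0.235 and Spearman's rho of 0.257, and 57.6% of probes had 1 sign on both. These are correlations across probes, which are not independent replicates, and a dye effect shared by the arrays also raises them. The count of 85 probes rests on the spread borrowed from all probes, since each probe has 1 residual degree of freedom, and it was 0 with Agilent's processed signals, with an offset of 0, with the series matrix values, with a trended and robust prior and in both fits of the separate channels. At an unadjusted p under 0.05 limma gave 2528 probes, and 2351, 2471, 2355, 2143, 2231 and 1510 in those settings.

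**Figure D1:**
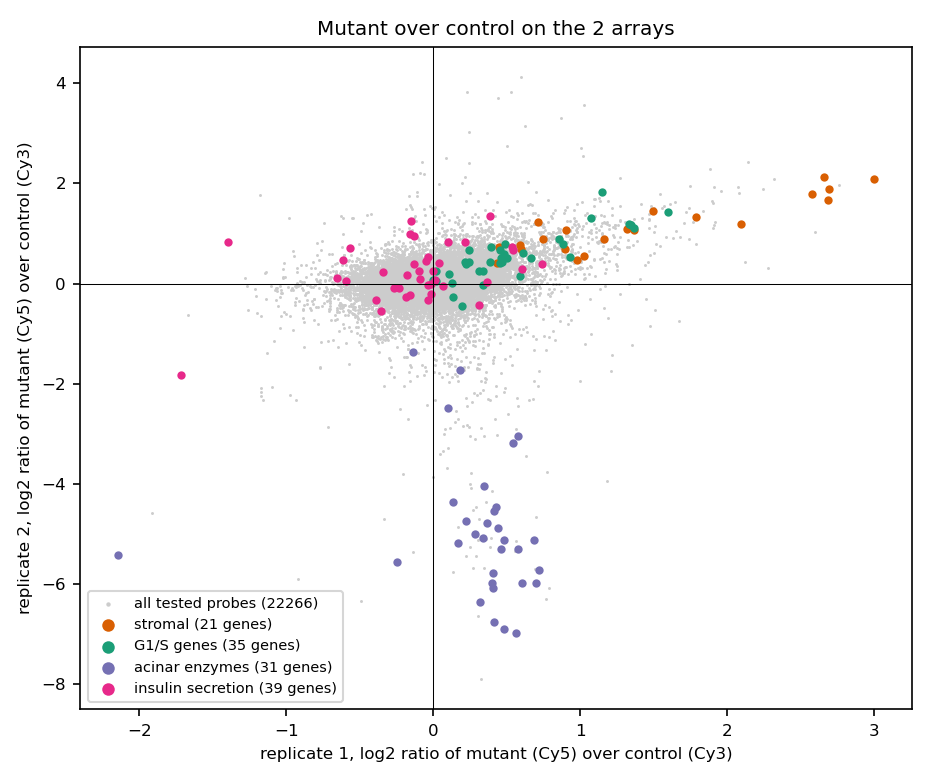
Log2 ratio of mutant over control for each tested probe on the replicate 1 array (horizontal axis) and the replicate 2 array (vertical axis), with the genes of 4 lists in colour, 1 probe per gene. The 21 stromal genes lie above 0 on both arrays, while all 31 acinar genes lie below 0 on the replicate 2 array and 28 of them above 0 on the replicate 1 array.

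Genes of the stroma stood highest among 28 gene lists. All 21 measured markers of stellate cells and fibroblasts were higher on both arrays, with median log2 ratios of 1.16 and 1.07. In this list 9 genes rose and 12 did not pass over all probes, and 21 rose when adjusted over the list alone. The list rose with limma's camera at a preset correlation (adjusted p = 4.33e-26), and its adjusted p = 0.639 with an estimated correlation. Duct markers had medians of 0.53 and 0.70, and 15 of 17 were higher on both arrays. Of these, the tetraspanin gene Tspan8 (1.41 and 1.59) and Spp1, which encodes osteopontin (1.77 and 1.23), rose over all probes, and 11 rose when adjusted over the list alone. Endothelial markers had medians of 0.37 and 0.58. Vwf, which encodes von Willebrand factor, rose by 1.60 ± 0.020 (SD, n = 2) on the brighter of 2 probes, while its other probe did not pass (mean 0.24), and 13 of 17 rose and 1 fell when adjusted over the list alone. All 6 measured Schwann cell and neural markers were higher on both arrays, with medians of 0.51 and 0.45. None of them passed over all probes and 4 rose when adjusted over the list alone, and Gap43, a growth cone gene, had ratios of 1.15 and 0.76. Leukocyte markers had medians of 0.13 and 0.47, with 0 of 22 past the test over all probes and 2 when adjusted over the list alone. Camera adjusted p values at the preset correlation were 7.20e-11 for duct, 2.05e-08 for endothelial, 6.37e-05 for Schwann cell and 0.00331 for leukocyte markers, and adjusted p = 0.639 with an estimated correlation for each of the 4. The leukocyte list also did not pass with median centring. Adipose markers did not pass, with medians of 0.04 and 0.06 over 5 genes (camera adjusted p = 0.826) and 0 when adjusted over the list alone. Haemoglobin and other erythroid genes had medians of -0.16 and -0.52 over 5 genes, of which 0 passed over all probes and 1 fell when adjusted over the list alone. The erythroid list was lower with camera at the preset correlation (adjusted p = 0.00464), its adjusted p = 0.639 with an estimated correlation, and with median centring its mean ratio was 0.41 and it did not pass (adjusted p = 0.281).

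Genes of the G1/S transition and DNA replication, which E2F factors activate, were mostly higher in the mutant, and 5 of them rose over all probes. Of 35 measured, 32 were higher on both arrays and 0 lower on both, with median log2 ratios of 0.46 and 0.50, which are 1.37-fold and 1.42-fold. The MCM helicase genes Mcm4 (chromosome 16, 15624372 to 15624431, mm9; mean 1.51 ± 0.12), Mcm2 (1.26 ± 0.095) and Mcm6 (1.25 ± 0.13) rose (SD, n = 2 each; limma adjusted p from 0.0297 to 0.0446). Mcm5 and the licensing factor gene Cdt1, named after their values were seen, complete these 5, and 30 did not pass, while 21 rose when adjusted over the list alone. Mcm3 did not pass, with ratios of 1.15 and 1.82. The list rose with camera at the preset correlation (adjusted p = 2.64e-15), and its adjusted p = 0.639 with an estimated correlation. Among genes of the Rb and E2F families with their cyclins and kinases, 11 of 17 were higher on both arrays, with medians of 0.12 and 0.14. E2f1 had ratios of 0.97 and 0.93 (limma adjusted p = 0.0647), the cyclin D1 gene Ccnd1 0.64 and 1.20, and the Rb relative Rbl1 0.53 and 0.65. None passed over all probes and 3 rose when adjusted over the list alone, with camera adjusted p = 0.0146 at the preset correlation, adjusted p = 0.639 with an estimated correlation and 0.129 with median centring. The list of G2/M genes, which act in mitosis, did not pass. Its medians were -0.03 and -0.22, with 3 of 16 higher and 10 lower on both arrays (camera adjusted p = 0.172; mean ratio 0.47 with median centring). Mad2l1, a spindle checkpoint gene, had ratios of 0.70 and 0.66, the mitotic kinase gene Pbk -0.36 and -0.46, and the survivin gene Birc5 -0.06 and -0.48, and 1 G2/M gene rose when adjusted over the list alone. CDK inhibitors and senescence genes had medians of 0.01 and 0.05 over 16 genes (camera adjusted p = 0.633), with Igfbp3 at 0.86 and 0.76 and the p18 gene Cdkn2c at -0.48 and -0.60. None passed over all probes, and 2 rose and 1 fell when adjusted over the list alone. Targets of p53 had medians of 0.22 and 0.11 over 23 genes (camera adjusted p = 0.269, and 0.0429 with both channels above background), with Phlda3 at 1.32 and 0.87, and 3 rose and 1 fell when adjusted over the list alone.

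The insulin genes and the glucagon gene differed between the 2 arrays by more than their mean ratios. Ins1 had ratios of -0.15 and 1.25, Ins2 -0.57 and 0.71, and the glucagon gene Gcg 1.45 and -0.30, and none passed (limma adjusted p = 0.594, 0.958 and 0.649). Pdx1, a beta cell transcription factor gene, had ratios of -0.68 and 0.25. Beta cell transcription factors had medians of -0.11 and 0.10 over 18 genes (camera adjusted p = 0.217), and 0 passed over all probes or when adjusted over the list alone. In the insulin secretion list, medians were -0.09 and 0.23 over 39 genes (camera adjusted p = 0.868, and 0.00349 with median centring), and Trpm5 was the 1 gene that fell, over all probes and when adjusted over the list alone. Genes of the other endocrine cells were higher, with medians of 0.98 and 0.20, and 10 of 16 were higher on both arrays. Ppy, the pancreatic polypeptide gene, had ratios of 2.59 and 1.02, Pyy 1.55 and 0.76, and Hhex, a transcription factor gene of delta cells, 1.14 and 0.82. None passed over all probes and 5 rose when adjusted over the list alone, with camera adjusted p = 5.13e-05 at the preset correlation and adjusted p = 0.639 with an estimated correlation. The list of genes that beta cells normally keep low or express on dedifferentiation had medians of 0.71 and 0.11. Its 2 genes that rose were the chemokine gene Cxcl12 (mean 1.20 ± 0.025) and the retinaldehyde dehydrogenase gene Aldh1a3 (1.12 ± 0.12; SD, n = 2 each). Aldh1a3 only just passed (limma adjusted p = 0.0499) and was well above background in the control channel on 1 of the 2 arrays. It passed in 4 of 9 other settings, with means from 1.12 to 2.41. The other probe of Cxcl12 did not pass (mean 0.78), and 7 of 18 rose when adjusted over the list alone. The growth factor receptor gene Pdgfra (0.90 and 1.06), which is also in the stromal list, did not pass and was not well above background in the control channel on either array. It was at least 1.88-fold brighter in the mutant channel. The bound compares normalized channel levels and is open to dye bias. Camera gave this list adjusted p = 7.52e-06 at the preset correlation and adjusted p = 0.639 with an estimated correlation. Stromal markers were higher on the same arrays (medians 1.16 and 1.07), and whether these transcripts come from beta cells or other cells was not tested.

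**Figure D2:**
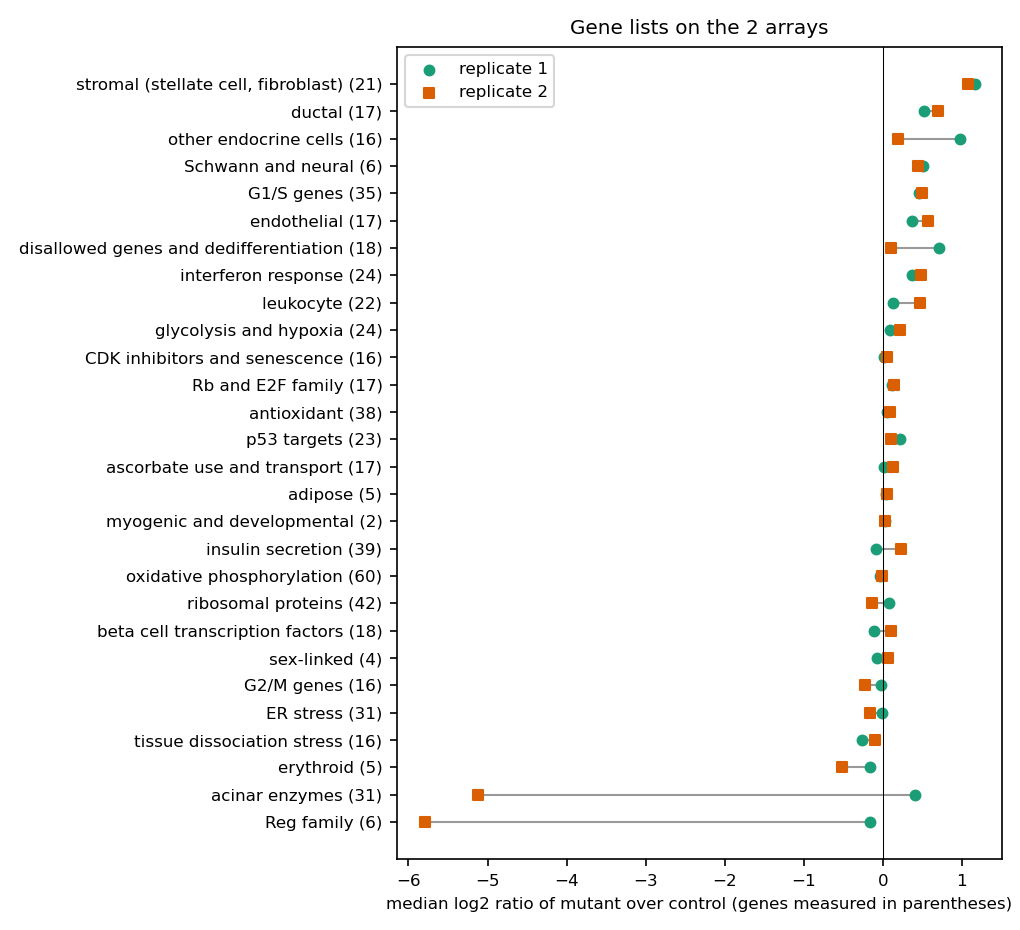
Median log2 ratio of mutant over control for each of the 28 gene lists on the replicate 1 array (circles) and the replicate 2 array (squares), with the number of genes measured beside each name. The stromal list is highest at 1.16 and 1.07, and the acinar and Reg lists part between the arrays, at 0.41 and -5.12 and at -0.17 and -5.80.

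Digestive enzyme genes of acinar cells divided the 2 arrays. Their median ratio was 0.41 on the replicate 1 array and -5.12 on the replicate 2 array, a 34.7-fold lower level in the mutant sample of replicate 2. On the replicate 1 array 28 of 31 were higher, and on the replicate 2 array 31 of 31 were lower. Amy2a5, a pancreatic amylase gene, had ratios of 0.48 and -6.91, and the carboxypeptidase gene Cpb1 0.56 and -6.97. Genes of the Reg family, secreted lectins that acinar cells make after injury, had medians of -0.17 and -5.80 over 6 genes, with Reg1 at 0.30 and -6.65. The acinar list's median log2 level was 15.8 in the control and 16.1 in the mutant sample of replicate 1, 17.1 in the control sample of replicate 2 and 11.5 in the mutant sample of replicate 2. The Reg list's levels in the same order were 11.7, 11.3, 15.5 and 10.5. No acinar or Reg gene passed over all probes, and 1 acinar and 0 Reg genes fell when adjusted over the list alone. Camera at the preset correlation gave adjusted p = 1.19e-12 for the acinar and 0.000137 for the Reg list, both lower, and adjusted p = 0.639 with an estimated correlation for each. The values at the preset correlation do not show that the 2 pairs agree, since 28 acinar and 3 Reg genes had opposite signs on the arrays. Of the 330 probes at least 2-fold lower in the mutant on the replicate 2 array, 43 belonged to genes of these 2 lists. Without the genes of the 2 lists, an alternative chosen after the data were seen, 174 of 22223 tested probes rose and 11 fell, with all 85 earlier probes among them. This fit borrows its spread from probes without these widely scattered genes. So the larger count need not mean more changes in other genes.

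The samples of replicate 2 also differed in Xist, the RNA of the inactive X chromosome of female cells. Its brighter probe had ratios of 0.37 on the replicate 1 array and -1.22 on the replicate 2 array, where it was not well above background in the mutant channel. Ratios of the Y-linked genes were -0.45 and 0.21 for Ddx3y, -0.18 and 0.69 for Eif2s3y, and 0.04 and -0.08 for Uty, whose control channel was not well above background on either array. Ddx3y and Eif2s3y were well above background in both channels on both arrays. The brighter Xist probe was so in both channels on the replicate 1 array and in the control channel on the replicate 2 array. Whether samples held RNA of both sexes was not tested. The sex-linked list did not pass (medians -0.07 and 0.07 over 4 genes; camera adjusted p = 0.637), and 0 passed when adjusted over the list alone. On the replicate 1 array alone 202 probes were at least 2-fold higher and 44 lower in the mutant, with no test. The stromal list's median was 1.16 there and that of the G1/S list 0.46.

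**Figure D3:**
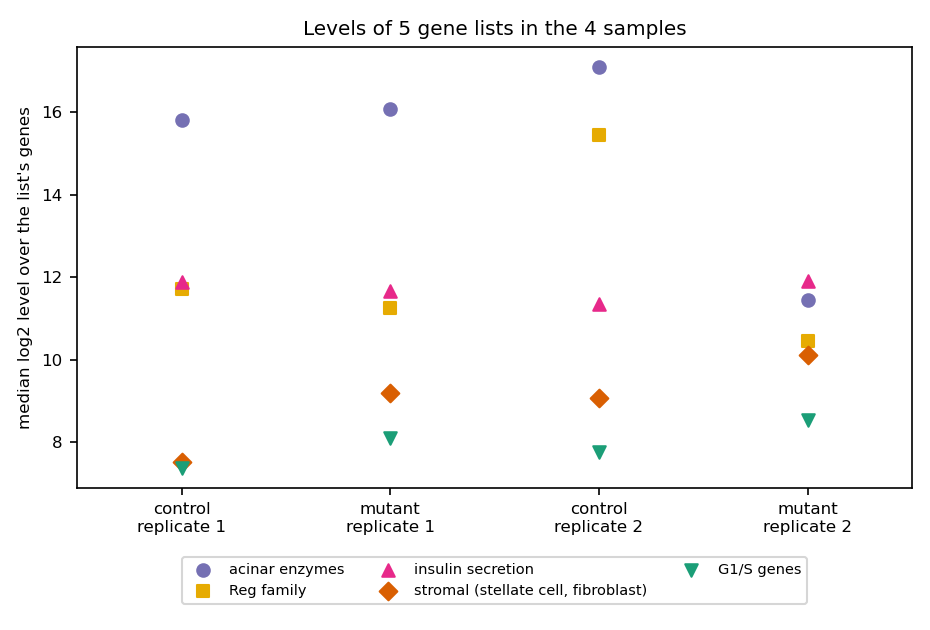
Median log2 level of 5 gene lists (vertical axis) in each of the 4 samples, after loess within arrays and quantile normalization of mean intensities between arrays. Levels of 1 list can be compared between samples, not those of different lists. The acinar list is at 11.5 in the mutant sample of replicate 2 and from 15.8 to 17.1 in the other 3 samples, and the stromal list is at 9.07 in the control sample of replicate 2 and 9.18 in the mutant sample of replicate 1.

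Of 24 interferon response genes 18 were higher and 0 lower on both arrays, with medians of 0.37 and 0.49, and 1 passed over all probes. This was Oasl2, an antiviral gene, which rose by 1.27 ± 0.00229 (SD, n = 2; limma adjusted p = 0.0419). Bst2, which encodes tetherin, had ratios of 0.78 and 1.22, and the ubiquitin-like modifier gene Isg15 0.62 and 0.96. In this list 11 genes rose when adjusted over the list alone, with camera adjusted p = 7.43e-08 at the preset correlation and adjusted p = 0.639 with an estimated correlation. Immediate early and heat shock genes that tissue dissociation induces were lower, with medians of -0.27 and -0.10 and 9 of 16 lower on both arrays. Besides Egr1 and Fos, Jun had ratios of -0.65 and -1.26 and Hspa1a -0.70 and -0.38. In this list 4 genes fell and 1 rose when adjusted over the list alone, with camera adjusted p = 0.00265 at the preset correlation and adjusted p = 0.639 with an estimated correlation, and the list's mean ratio was 0.36 with median centring.

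The lists of redox defence and energy metabolism did not pass, but antioxidant and oxidative phosphorylation genes passed camera with median centring, and antioxidant genes also with no filter on dim probes. Antioxidant genes had medians of 0.06 and 0.09 over 38 genes (camera adjusted p = 0.232). Sod3, the extracellular superoxide dismutase gene, was the 1 gene that rose, over all probes (mean 1.17 ± 0.039, SD, n = 2; limma adjusted p = 0.0446) and when adjusted over the list alone. The metallothionein genes Mt2 (-0.34 and -2.04) and Mt1 (-0.05 and -1.66) were far lower on the replicate 2 array only. Genes of ascorbate synthesis, transport and use had medians of 0.01 and 0.13 over 17 genes (camera adjusted p = 0.344), and 0 passed over all probes or when adjusted over the list alone. P4ha2, a prolyl hydroxylase gene, had ratios of 0.31 and 0.29. Oxidative phosphorylation genes had medians of -0.04 and -0.01 over 60 genes (camera adjusted p = 0.217), and 0 passed over all probes or when adjusted over the list alone. Glycolysis and hypoxia genes had medians of 0.09 and 0.22 over 24 genes (camera adjusted p = 0.444), and 1 fell when adjusted over the list alone. Endoplasmic reticulum stress genes had medians of -0.01 and -0.17 over 31 genes (camera adjusted p = 0.0643), with Chac1 at -0.71 and -2.86 and Herpud1 at 0.04 and -1.38, and 0 passed when adjusted over the list alone. In this list 8 genes were higher and 11 lower on both arrays. Chac1, Herpud1, Mt1 and Mt2 were lowest on the replicate 2 array, where acinar genes were also far lower (median -5.12). Whether these falls share a cause was not tested. Ribosomal protein genes had medians of 0.08 and -0.14 over 42 genes (camera adjusted p = 0.188), and the 2 measured genes of the myogenic and developmental list medians of 0.03 and 0.03 (camera adjusted p = 0.993), with 0 genes past the test in either list, though the ribosomal protein list passed camera with median centring.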

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

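The stromal pattern was taken up, and its tests and those of the low acinar level in the mutant sample of replicate 2, of a genotype-linked acinar fall and of cycling cells were chosen, only after the results were seen. Agilent's spike-in control spots, which the comparison does not use, are mixed at known ratios in the 2 dyes. A line of observed on expected log10 ratio over them had an intercept of 0.293 on the replicate 1 array and 0.0858 on the replicate 2 array, which are 1.96-fold and 1.22-fold towards Cy5, with slopes of 0.911 and 0.913.

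Stromal genes were higher in both mutant samples. GC content of the probes is argued against, since 0% of 10000 lists matched on GC content and brightness had a median as high (the central 95% of them ended at 0.14, against 1.02). Loess had already centred the ratios at each brightness, so brightness itself was not put to the test. A smaller share of endocrine cells, with the mix of the other cells kept, would raise the markers of the other cells alike. The stromal median exceeded that of 62 duct, endothelial, leukocyte and Schwann genes by 0.59 (95% bootstrap interval over genes, not samples, 0.35 to 1.16). The bound for this was set after the list medians were seen. So the difference describes these 2 pairs, and a smaller endocrine share is not ruled out as part of the cause. More stromal tissue in the mutant samples stays open: 100% of the 21 measured genes were higher on both arrays, but this restates the pattern and does not bear on its cause. An effect of the genotype, of how cleanly islets were picked, and of the dyes cannot be told apart with 2 arrays of 1 dye orientation, and the control sample of replicate 2 was at 9.07 on the log2 scale, close to the mutant sample of replicate 1 at 9.18.

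Acinar genes were far lower in the mutant on the replicate 2 array only. On the replicate 1 array the list's median ratio was 0.41 (95% bootstrap interval over genes, not samples, 0.34 to 0.46). This is part of the pattern itself, so an effect of the genotype that only 1 of 2 pairs shows stays open. Acinar tissue in the control sample of replicate 2 as the cause is left undecided, since that sample exceeded the highest of the other 3 by 1.01, between the bounds set for and against it. Less acinar tissue in the mutant sample of replicate 2 is consistent with the levels, since it lay at -4.36 relative to the lowest of the other 3 samples. The Reg list's median level was 15.5 in the control sample of replicate 2 against 10.5 to 11.7 in the other 3, but its member Reg1 was far lowest in the mutant sample of replicate 2 (11.1 against 15.9 to 17.7), and no explanation for the Reg genes was tested.

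G1/S genes were higher in both mutant samples. GC content of the probes is argued against, since 0% of 10000 lists matched on GC content and brightness had a median as high (the central 95% of them ended at 0.11, against 0.46). Brightness was not put to the test here either, because of loess. The G2/M median was -0.16 (95% bootstrap interval over genes, not samples, -0.23 to 0.12), below 0.23, which is 0.5 of the G1/S median. The measured G2/M genes thus did not rise with the G1/S genes. Only 16 of the 35 listed G2/M genes were measured, and the bound was set after the results were seen. A larger share of cycling cells is therefore not excluded. A dye bias of single probes cannot be told apart from a change, because only 6 other probes of 5 genes were tested, with a median of 0.15 on the lower array (95% bootstrap interval -0.08 to 0.55) and 4 of 6 higher on both arrays. An effect of the genotype on E2F targets stays open, though the rise runs against the hold on S phase entry described above for Rb that is not phosphorylated. So does a changed mix of cells, since stromal (1.16 and 1.07), duct (0.53 and 0.70) and endothelial (0.37 and 0.58) markers were higher on the same arrays, and neither was tested beyond these values.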

How the results depend on the processing

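Leaving out acinar and Reg genes or population outlier spots was chosen after the data were seen. The number of probes past threshold, 85, became 0 with Agilent's processed signals, an offset of 0, the series matrix values, a trended and robust prior, and the separate channels with the array as a replicate block (intraspot correlation 0.221) and with no replicate block. It became 6735 with median centring (6664 higher, 71 lower), 355 with no filter on dim probes (323 and 32), 247 at an adjusted p under 0.1 (233 and 14), 1035 by Agilent's own p on both arrays (791 and 244, and 180 more with opposite signs) and 185 without acinar and Reg genes, and the cause was not tested. In the other 5 settings the count stayed within 1.5 times, and 84 of the 85 were shared with no background subtraction, 69 with both channels above background and 82 with outlier spots kept, while quantile normalization leaves the ratios as they are. The 118 probes changed at least 2-fold on both arrays became 617 with processed signals, 341 with an offset of 0, 755 with median centring, 614 with the series matrix values and 436 at 1.5-fold, and on 1 array alone from 246 to 660. The 14 lists past the threshold became 0 with an estimated correlation and with fry, and stayed within 1.5 times in 13 other settings. With median centring Rb1 passed (mean 1.04), the correlation of the arrays rose from 0.235 to 0.421, and the mean ratios of erythroid (0.41), oxidative phosphorylation (0.88), dissociation stress (0.36) and ribosomal protein genes (0.94) turned positive. Of these, oxidative phosphorylation (adjusted p = 0.00067) and ribosomal protein genes (0.000112) gained a camera call, and erythroid genes lost theirs (0.281). Those shifts are to be read against medians of 0.39 and 0.84 for all tested probes. Without replicate 2 the acinar mean was 0.30, against -4.94 without replicate 1, and Rb1 lay between 0.14 and 0.48. Of 1252 values of named genes under other settings, 98 lost and 89 gained the threshold and 0 changed sign while past it in either setting (others below it did, such as H2bc4 from -0.79 to 0.11 with median centring), and of 417 list values 30 lost and 4 gained it with their sign kept. The losses were all 14 lists with an estimated correlation and with fry, and Rb and E2F family and leukocyte genes with median centring, and the gains were insulin secretion and antioxidant genes with median centring, antioxidant genes with no filter on dim probes, and p53 targets with both channels above background. Replicate numbers pair mutant and control through the shared array, and the ratio itself is that block. A sample left out leaves 1 array and no test, and under 0.5 of spots were well above background in each channel, which limits what dim genes can show.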

Other observations

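The tests of satellite, histone and Malat1 probes below were chosen after the data were seen. Outside the gene lists, 7 probes with the sequence of the mouse major satellite, the repeat of pericentromeric heterochromatin, were higher in the mutant. The repeat sequence was written from general knowledge and not checked against a repeat library here. Each of the 7 shares 22 to 51 words of 10 bases with it, so they can bind the same RNA and count as 1 measurement. Their median log2 ratios were 1.95 and 1.85, which are 3.88-fold and 3.62-fold, and 7 of 7 rose with limma (adjusted p 0.0262 for the highest, with a mean of 2.20 ± 0.17, SD, n = 2). With processed signals the medians were 2.50 and 2.27 and 0 probes passed, and with median centring they were 2.48 and 2.85.

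Genes of the replication-dependent histones had ratios opposite in sign to those of the G1/S list with loess, but not with median centring. Over 35 such genes the medians were -0.22 and -0.43, 26 were lower and 1 was higher on both arrays, and 0 passed with limma, while with median centring the medians were 0.27 and 0.56, below those of all tested probes in that setting (0.39 and 0.84). H2bc4 had ratios of -0.78 and -0.81, H2ac18 -0.88 and -0.69, and H3c15 -0.81 and -0.72. The 4 probes of the nuclear RNA Malat1, of which 3 carry the name NEAT2, had medians of -1.13 and -2.20. The probe named Malat1 and 1 of those named NEAT2 lie at the same position, so the 4 are not separate measurements. None of them passed with limma, 3 passed with median centring and 4 with no filter on dim probes, and all 4 were lower on both arrays.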
